A study of Arabidopsis thaliana with 3 samples.

How the data were processed

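RNA from pooled first true leaves of untreated Arabidopsis thaliana Col-0 plants was sequenced in 3 libraries, which the labels give as replicates of 1 group. Per the labels' protocols, RNA was treated with a DNase and made into Illumina TruSeq libraries. The labels do not say whether the pools came from separate plantings, so every p-value over libraries measures only the spread between these samples, which may be technical. The submitters' processing notes name CASAVA 1.8.2, GSNAP and the build TAIR10. The tool that classified the events and the strandedness of the libraries are not given in the sources used here.

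The deposited table holds raw read counts by the authors, with no normalization: for each alternative splicing event and library, the counts of reads for the alternative form and of other reads, in 6 columns. It lists 62,909 events in 14,496 genes, and each event has at least 1 alternative read in every library. Events absent from it cannot be told from events below that limit. The level of an event was computed as its alternative reads in percent of its alternative and other reads. At all 9092 junctions with several events, these share 1 total in every library. The levels of all 58,509 nuclear events between neighbouring exons were therefore read as shares of junction reads, which could not be checked at junctions with 1 event. The other 4340 nuclear events (skipped exons, introns inside exons and events between exons that are not neighbours) carry a total shared by all such events of a gene, and their levels are shares of gene-wide reads. Reads that skip an exon are not part of the totals of the junctions they span. How reads inside introns were counted is not given in the sources used here, so the absolute level of a retained intron depends on a rule that is unknown.

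The class codes are not defined in the labels, and their reading rests on coordinates. IR lists neighbouring exons without coordinates and was read as intron retention. ALTA and ALTD move the acceptor or the donor, ALTP moves both, SKIP joins exons that are not neighbours, and CRIN removes sequence from inside 1 exon. Of the CRIN events, 2477 lie inside an exon of the transcript chosen for coordinates, 269 inside an exon of another annotated transcript only, and 25 inside no annotated exon, while 22 are in genes without a chosen transcript. CREX, SKAD and CPLX were only counted and listed. The reference used was TAIR10.1 with the RefSeq annotation. Its nuclear chromosomes have the lengths of TAIR10, and coordinates of shifted sites and skipped exons are as deposited. Intron coordinates were taken from the annotated transcript whose introns best abut the listed sites: 97.5% of the shifted sites abut the numbered intron of that transcript, against 85.2% for the first transcript. Positions are 1-based. Organellar events (60 in 39 genes) were kept out of all comparisons.

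Duplicates were defined from 1 protein (of the lowest-numbered coding transcript) of each of 27,444 nuclear genes with BLASTP (blast 2.17.0, E at most 1e-10, at least 50% of both proteins aligned, 20 targets kept per query). Genes with another such protein counted as duplicated (20,385), the rest as single-copy (7059). Reciprocal best hits gave 6752 pairs, of which 2988 had both members in the table and 2927 could be used. Introns of a pair were taken as homologous when they had the same phase at the same aligned codon, each intron once (gap opening 11, extension 1, biopython 1.88). This gave 15,396 introns with usable positions.

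Events were tested for equal levels in the 3 libraries by a chi-square test of homogeneity with Benjamini-Hochberg adjustment at 0.05. This test sets the differences between libraries against read-counting error alone and takes reads as independent, so its calls include any ordinary variation between libraries. Classes were compared by permutation over events (100000 resamples, two-sided) of the ranks of their mean levels. This tests a difference in mean rank, while the differences in points are between medians. Events of 1 class are not replicates. Shares of genes with an event were compared by Fisher's exact test and by 10000 permutation draws within strata of depth decile and intron number, with 12 or more introns in 1 stratum. Whether a gene was listed at all was matched on intron number alone, since unlisted genes have no depth, and gene lists on depth alone. Gene lists and the duplicated against single-copy test count genes with a junction-level event, and ask which of them also have a shifted site, a skip or a CRIN event. Pairs with an event in 1 member only were compared with random pairs matched on the same strata (10000 draws, two-sided). Homologous introns were matched on depth decile alone and drawn singly. Introns of 1 gene pair were thus taken as independent, so their ranges and p-values may be too small. At homologous introns with the same class in both members, the difference of log2 odds was taken within each library, with 0.5 added to event reads, and tested over the 3 libraries with limma 3.58.1 (moderated one-sample test, Benjamini-Hochberg at 0.05). Reads of all events of the class at an intron were summed first, and shifted sites were not matched by position between members. Levels of shifted sites are relative to the site annotated in each gene. A sign test over 3 libraries alone cannot go below an exact p of 0.25, so the limma calls rest on the spread that limma pools over introns. Expression of a member was the CPM of its median junction, scaled to the library's summed junction reads, with 1 added before log2, and was tested in the same way. Only junctions with a listed event count here, and their totals hold retained reads and leave out skip reads. Tandem pairs lay at most 10 genes apart. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

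The tests, the 15 gene lists, the 28 named duplicate pairs, the rule for naming genes and most alternatives were fixed before the data were examined. Named are up to 6 members of each list with the most reads per junction, each preset pair with an intron compared (with at least its largest called difference, others in counts), the 10 other intron pairs with the largest level difference among called ones, the 5 events of each class with the most alternative reads, the 5 genes with the most events, and the 5 events with the largest spread between libraries among those past the homogeneity test. Preset pairs that are not reciprocal best hits were fitted together with all others. Exceptions are named where they occur. 1 of the 10 intron pairs is not reported here. The preset alternatives were a minimum of 10 alternative reads in each library, leaving out each library, a pseudocount of 2.5 (5 CPM for expression), stricter pairs (60% identity over 70% of both proteins), other matching, adjacent genes as tandem, TMM factors of edgeR 4.0.16 and counting each gene once per class. Alternatives added after seeing the data were a minimum of 5 expected reads in the homogeneity test, skip reads added to the totals of spanned junctions, pairs under 90% identity, stricter pairs for expression and gene lists counted by a shifted site at 10% or more.

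The summed junction reads were 34653545, 33164071 and 62677541 in replicates 1, 2 and 3. At the median junction, a count of 0 allows a level of up to 1.66%, 1.70% and 0.990% (3 counts). Reads without molecular identifiers are not independent molecules, so intervals of shares (exact binomial, 95%) and floors cover counting error only. Intervals of medians are from bootstrap draws over introns, and those of odds ratios from the standard error of the log odds, both at 95%. Genes with a near-identical copy may share reads, and overlapping genes cannot be separated without strand.

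The tests were tested on simulated data with known changes. With 200 of 4525 intron pairs shifted, the pair test called 34% of those shifted by 2 log2 units and 99% of those shifted by 4, and 0.347% of the unshifted ones. With 1131 pairs at each of these sizes shifted, it called 85.9% and 98.6%, and 3.45% of the unshifted ones. The simulated spread between libraries beyond counting error was set, the same for all introns, and not taken from the data. Some real pairs with many reads spread more, so these shares may be too favourable. The homogeneity test over 62,740 events called 56% of the events whose odds changed 2-fold in 1 library, 100% at 4-fold, and 0.0208% of the unchanged ones. The changed events were drawn only from those with at least 100 alternative reads over the libraries and a level under 50%. These shares therefore do not hold for events with few reads. Without signal, 3 of 100 draws of the pair test for events in 1 member and 7 of 100 draws of the matched share test gave a permutation p under 0.05.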

Results

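The data describe alternative splicing in first true leaves of Arabidopsis thaliana Col-0, the reference accession, in 3 libraries of 1 group. The series title names qualitative and quantitative divergence of splicing between duplicated genes as its subject, so the comparisons are between event classes, between duplicated and single-copy genes and between members of a pair. The nuclear part of the table held 62,849 events in 14,457 genes. Over 46,345 junctions the libraries held 34653545, 33164071 and 62677541 reads, with a median of 181, 176 and 303 reads per junction and of 7, 5 and 11 alternative reads per event. Values are means ± SD over the 3 libraries (n = 3), and a level is the alternative form's share of reads.

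Retained introns (class IR) made up most of the listed leaf events, with 43,194 of 62,849 (68.7%, 95% interval 68.4 to 69.1%). Shifted acceptors (ALTA) followed with 8817 (14.0%), shifted donors (ALTD) with 4986 (7.93%) and introns inside exons (CRIN) with 2793 (4.44%). Shifts of both sites (ALTP, 1500 events, 2.39%) and skipped exons (SKIP, 995 events, 1.58%) were rarer, and the classes CREX, SKAD and CPLX held 316, 139 and 109 events. Of the genes, 95.8% had a retained intron, 42.8% had nothing else, and 57.2% had another class. The genes with the most events were PRP4 (AT4G38770, a proline-rich protein) with 88, UBQ10 (AT4G05320, polyubiquitin) with 68, AT1G67870 with 60, CA1 (AT3G01500, a carbonic anhydrase) with 53 and LHCB1.3 (AT1G29930, also CAB1, a light-harvesting protein) with 43. CRIN accounted for 87 of the events of PRP4, 65 of UBQ10, 55 of AT1G67870 and all 43 of LHCB1.3. The median level of CRIN events was 0.150% ± 0.0233 of gene-wide reads. Their ends were not checked for splice-site sequence, so how many are spliced introns is not known. They still count in the shares of gene lists and of duplicated genes below. In CA1 the events were spread over 9 IR, 10 ALTA, 10 ALTD, 10 ALTP and 10 SKAD entries, 2 skips and 2 CRIN. Counting each gene once per class lowered the IR share to 51.6%.

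**Figure D1:**
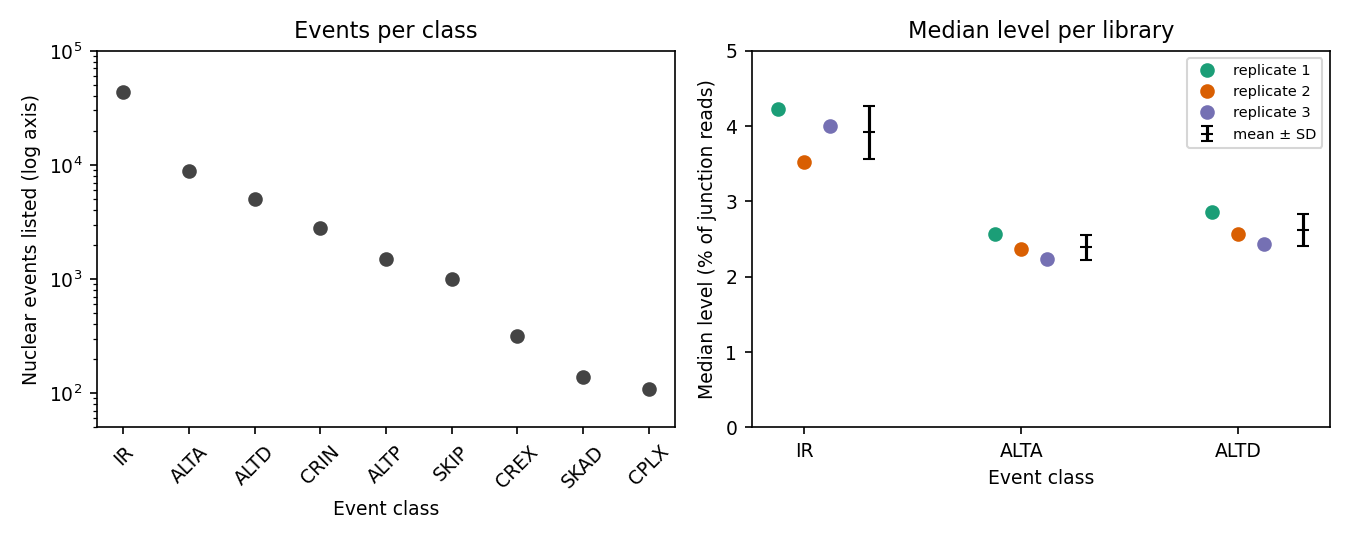
Left, nuclear events per class as points on a log axis, from 43,194 IR events to 109 CPLX events. Right, the median level of IR, ALTA and ALTD events in percent of junction reads for each replicate, with the mean ± SD over the 3 libraries beside them; replicate 2 had the lowest IR median, 3.53%.

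Ranked within each class by alternative reads, an order that favours abundant transcripts, several of the leading events carried nearly all reads of their junction. Intron 9 of CA1 (chromosome 3, 194892 to 195178, coding region) was retained at 95.4% ± 0.496, and intron 3 of EXPA1, an expansin (AT1G69530, chromosome 1, 26143035 to 26143108), at 99.0% ± 0.204. In RCA, Rubisco activase (AT2G39730), intron 6 (chromosome 2, 16571067 to 16571190) was retained at 15.5% ± 1.08, and a donor that adds 11 nt (16571180 to 16571190) reached 35.4% ± 1.05. Further retained introns with many reads lay in AT4G13495 (60.8% ± 3.14) and LpxC3 (AT1G25054, 55.0% ± 4.44), whose coordinates were not assigned. LpxC3 also held a CPLX event among the 5 with the most reads, at 0.966% ± 0.0764. A 3-nt shorter exon at an acceptor of PSBQA, a photosystem II protein (AT4G21280, chromosome 4, 11335092 to 11335094), had 98.4% ± 0.516 of the junction reads, and a 4-nt longer exon in PSAN, a photosystem I subunit (AT5G64040, chromosome 5, 25628810 to 25628813), had 99.5% ± 0.250. Shifted acceptors in AT2G26500 (4 nt, 96.7% ± 0.168), CPN60B (AT1G55490, 25 nt, 98.7% ± 0.376) and PRXQ (AT3G26060, 3 nt, 91.6% ± 0.297) were also the main form.

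Among shifted donors the same held for RBCS3B, a Rubisco small subunit (AT5G38410, 15 nt removed at chromosome 5, 15377896 to 15377910, 99.7% ± 0.136), APE2 (AT5G46110, 4 nt, 98.5% ± 0.287), ACP4 (AT4G25050, 36 nt, 98.4% ± 0.367) and PIP1B, an aquaporin (AT2G45960, 4 nt, 98.0% ± 0.461). RBCS3B may share reads with its near-identical copy RBCS2B, so its value is uncertain. The leading CRIN events removed 73 nt from PMDH2 (AT5G09660, 9.22% ± 0.0672 of gene-wide reads), 89 nt from the 5' UTR of EXPA1 (18.4% ± 0.336), 297 nt from UBQ14 (AT4G02890, 26.6% ± 1.39), 75 nt from the 3' UTR of BBD1 (AT1G75380, 10.3% ± 0.848) and 78 nt from GLU1 (AT5G04140, 1.72% ± 0.0961). Those of PMDH2 and UBQ14 lie in an intron of the transcript used for coordinates and inside an exon of another annotated transcript. Both sites were shifted in HCEF1, a chloroplast fructose bisphosphatase (AT3G54050, 42.7% ± 1.14), SNG1 (AT2G22990, 95.9% ± 0.524), UBC8 (AT5G41700, 86.6% ± 1.28), eEF-1Bb1 (AT1G30230, 99.7% ± 0.185) and HMGB3 (AT1G20696, 92.4% ± 1.38). The leading CREX events were in PPH, pheophytinase (AT5G13800, 39.6% ± 1.77), ZAT (AT2G46800, 17.2% ± 0.656), AtkdsA1 (AT1G79500, 59.5% ± 5.52) and, as shares of gene-wide reads, AT5G64130 (2.65% ± 0.214) and BBD1 (0.352% ± 0.0416). The leading SKAD events, also over gene-wide reads, were in HST (AT3G11945, 7.07% ± 0.550), AT5G14030 (10.9% ± 0.620), SLP1 (AT1G07010, 6.33% ± 0.320), PFD1 (AT2G07340, 24.4% ± 1.24) and AT2G15910 (26.3% ± 0.291). Besides that of LpxC3, the leading CPLX events were in BGLU33 (AT2G32860, 40.9% ± 2.99), PAA1 (AT4G33520, 6.94% ± 1.21), AT4G09250 (27.3% ± 2.68) and AT1G25097 (4.26% ± 1.42).

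Acceptors moved most often by 3 nt and donors by 4 nt. Of 8817 shifted acceptors, 969 moved by 3 nt, the commonest length, with 645 of these removing and 324 adding exon sequence. Of 4986 shifted donors, 508 moved by 4 nt. The median shift was 13 nt for acceptors and 27 nt for donors, and 39.7% of the acceptors and 56.5% of the donors added sequence to the exon. The new acceptor ended in AG in 8111 of 8294 sites checked (97.8%), and the new donor began with GT in 92.3% and GC in 4.92% of 4672 sites. The share of acceptor shifts divisible by 3 was 36.1% in coding regions (95% interval 35 to 37.2%), 38.9% in 5' UTRs and 44.1% in 3' UTRs, and the share of donor shifts was 30.0% in coding regions (28.6 to 31.5%).

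**Figure D2:**
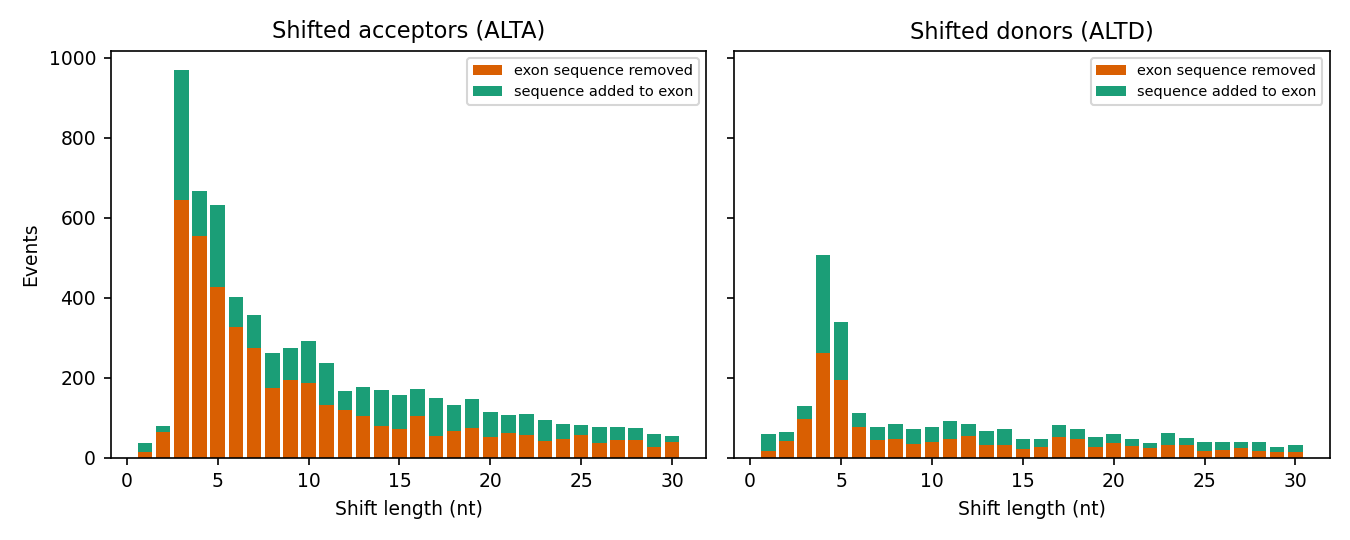
Number of shifted acceptors (left) and shifted donors (right) by shift length up to 30 nt, with the part that removes exon sequence below the part that adds it. Acceptors peaked at 3 nt (969 events) and donors at 4 nt (508 events).

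Skipped exons had low levels as deposited, because their totals are gene-wide, and several of the leading skips carried nearly all reads once set against the junctions they replace. The skip with the most reads joined exons 1 and 3 of AT5G54940 (skipped exon at chromosome 5, 22309216 to 22309280, 5' UTR) and had 50.3% ± 2.27 of gene-wide reads and 91.6% ± 3.20 of the skipping and flanking junction reads. In PSY, phytoene synthase (AT5G17230, chromosome 5, 5661386 to 5661430), the 2 values were 11% ± 0.265 and 99.0% ± 0.203. In PnsB2 (AT1G64770, chromosome 1, 24058589 to 24058655) they were 12.8% ± 0.724 and 99.3% ± 0.327, and in IAA8, an auxin-response repressor (AT2G22670, chromosome 2, 9636808 to 9636897), 14.1% ± 1.47 and 98.0% ± 0.978. MDAR1 (AT3G52880) had 13.2% ± 0.601 of gene-wide reads and no junction-level value. Of the 995 skips, 669 had both flanking junctions in the table. Their median level was 0.437% over gene-wide reads and 3.43% over junction reads, and 92 and 230 of them reached 10%. At junction level, 143 skips exceeded 50%.

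**Figure D3:**
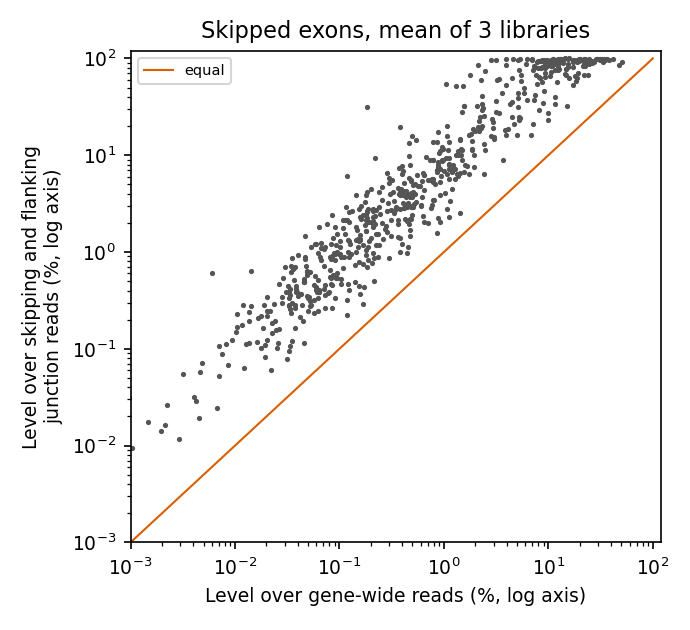
Each point is 1 of 669 skipped exons, with its level over gene-wide reads on the horizontal axis and over skipping and flanking junction reads on the vertical axis, both in percent on log axes and as means of 3 libraries. The line marks equal values; the median ratio of the vertical to the horizontal value was 8.12.

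Retained introns had the higher median level over all listed events, and the order of the classes turned with the read minimum. The median level was 3.92% ± 0.355 for IR, 2.39% ± 0.163 for ALTA and 2.62% ± 0.215 for ALTD. Differences in points are between medians, and the permutation p beside each tests mean ranks of the events. IR exceeded ALTA by 1.53 ± 0.317 points and ALTD by 1.3 ± 0.304 points in 3 of 3 libraries (permutation p = 1e-05 for both, the smallest possible; adjusted over 3 comparisons 1.5e-05). ALTD exceeded ALTA by 0.231 ± 0.0539 points (permutation p = 0.0425, adjusted 0.0425), a call that was lost without replicate 1 (0.200 points, permutation p = 0.0663). With at least 10 alternative reads in each library the medians were 11.3%, 18.3% and 17.2%, and IR lay below ALTA by -6.91 ± 0.706 points and below ALTD by -5.83 ± 0.788 points; ALTD minus ALTA was -1.08 ± 0.684 points (permutation p = 0.952). Levels of 50% or more were found for 3068 IR (7.10%), 699 ALTA (8.11%) and 415 ALTD events (8.53%).

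Levels correlated closely between the 3 libraries, and most of the events that differed by more than counting error were retained introns. Across events, which are not independent replicates, Pearson's r between libraries was 0.947, 0.954 and 0.966 and Spearman's rho 0.896, 0.906 and 0.925 (replicates 1 and 2, 1 and 3, 2 and 3). The homogeneity test, which allows for counting error alone, called 6336 events (10.1%), and 3586 of the 18,254 with at least 10 alternative reads in each library (19.6%). The calls included 5241 IR, 446 ALTA, 272 ALTD and 108 SKIP events. Of the called IR events, 2791 were lowest in replicate 2 and 3075 highest in replicate 1, while 60 of the 108 SKIP events were highest in replicate 2. Without replicate 1 the count of called events fell to 2042, without replicate 2 to 3693 and without replicate 3 to 3755. The 5 called events with the largest spread were retained introns of AT5G18065, AT3G43850, TAF4B (AT1G27720), AT3G21710 and ACO1 (AT2G19590), each at 100% in replicate 1 and resting on 6 to 18 alternative reads over the 3 libraries. A better covered case was intron 4 of CCA1, chosen for this after its values were seen, with 65.9%, 34.5% and 52.1% in replicates 1, 2 and 3 (2186 retained reads).

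Genes for splicing factors more often had a shifted site, a skip or a CRIN event than the remaining genes with a junction-level event. Of 19 SR protein genes, whose products act in splice-site choice, 17 had such an event, against 55.9% of the other genes (Fisher's exact p = 0.00235, adjusted 0.0153). Intron 2 was retained at 52.7% ± 2.49 in RS2Z32 (AT3G53500) and 16.9% ± 4.81 in RS2Z33 (AT2G37340), and at 33.8% ± 4.33 in RS40 (AT4G25500) and 30.0% ± 5.18 in RS41 (AT5G52040). In RS41 an acceptor that removes 3 nt (chromosome 5, 21133285 to 21133287) had 80.2% ± 1.21. Intron 10 of SR34 (AT1G02840) was retained at 37.1% ± 6.79 and intron 3 of SCL30 (AT3G55460) at 14.9% ± 2.64. Of 14 other splicing factors, 13 had such an event (Fisher's exact p = 0.00524, adjusted 0.0227). In U1-70K, a U1 snRNP protein (AT3G50670, intron 6, chromosome 3, 18827440 to 18828348), retention was 72.3% ± 5.45, in GRP7 (AT2G21660, intron 1, chromosome 2, 9265894 to 9266202) 44.1% ± 3.08, in GRP8 (AT4G39260, intron 1, chromosome 4, 18274568 to 18274850) 23.6% ± 3.81 and in SKIP (AT1G77180, intron 1) 22.7% ± 5.34. U2AF65a (AT4G36690) retained intron 11 at 52.7% ± 2.40, and U2AF65b (AT1G60900) intron 4 at 68.5% ± 9.36. Against genes matched on depth the shares were 89.5% and 61.1% for SR proteins and 92.9% and 62.1% for other splicing factors. The permutation p was 0.0165 and 0.0225, adjusted 0.0975 for both lists, so neither call held there although a gap remained. Intron number was not matched for gene lists, and a gene with more introns has more places for such events.

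All 23 photosynthesis genes with a junction-level event had a shifted site, a skip or a CRIN event, against 55.9% of the other genes (Fisher's exact p = 1.76e-06, adjusted 2.28e-05) and 71.0% of depth-matched genes (permutation p = 0.0013, adjusted 0.0169). Depth was matched by decile only. These genes had 30635 (CA2) to 443351 (RBCS1A) reads at their median junction and may exceed the matched genes in depth. The matched test therefore does not separate this list from depth. Among the 6 with the most reads per junction, the most retained intron was at 0.364% ± 0.105 in RBCS1A (AT1G67090, intron 2), 0.297% ± 0.120 in RBCS3B, 1.60% ± 0.442 in LHCA4 (AT3G47470), 1.64% ± 0.520 in LHCB5 (AT4G10340) and 2.25% ± 0.540 in LHCB3 (AT5G54270), light-harvesting proteins, and 15.5% ± 1.08 in RCA. Higher values were those of intron 9 of CA1 (95.4%), intron 1 of RBCS1B (AT5G38430, 100%, 354 reads) and intron 1 of CA2 (AT5G14740, 88.7% ± 13.4, 100 retained reads), the last 2 chosen after their values were seen. The median junctions of RBCS1B and CA2 had 56119 and 30635 reads per library, so these 2 introns hold few of the reads of their genes. In the other genes with a listed retained intron, the highest was at most 3.79% ± 0.515 (LHCB4.1). LHCB1.1, LHCB1.2, LHCB1.3, PSAD1 and PSAD2 had only gene-wide events and were left out of this test. When only shifted sites at 10% or more were counted, the share of photosynthesis genes lay -12.4 points from that of the other genes (adjusted p = 0.457, Fisher's exact test).

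Clock genes and light-signalling genes each had a shifted site, a skip or a CRIN event in 12 of 16 members (Fisher's exact p = 0.139, adjusted 0.301 for both lists). Among clock genes, CCA1 (AT2G46830, intron 4, chromosome 2, 19246385 to 19246862) was retained at 50.8% ± 15.7, PRR7 (AT5G02810, intron 3) at 55.8% ± 2.77, PRR9 (AT2G46790, intron 3) at 19.5% ± 3.79 with an 8-nt donor shift at 35.3% ± 2.15, and RVE4 (AT5G02840, intron 8) at 11.3% ± 5.65. Retention reached 99.3% ± 0.262 at intron 12 of TIC (AT3G22380) and 100% at intron 2 of ZTL (AT5G57360), a blue-light receptor, where all 1761 reads were retained ones. Among light and flowering genes, PIF4 (AT2G43010) retained intron 6 at 35.3% ± 2.88 and shifted a donor by 11 nt at 14.4% ± 1.08, CRY1 (AT4G08920) retained intron 3 at 16.9% ± 2.25, and FLM, a flowering repressor (AT1G77080), retained intron 2 at 40.8% ± 2.27 with a donor shift of 110 nt at 18.1% ± 1.63. CRY2 (AT1G04400) used an acceptor 67 nt downstream in its 5' UTR at 93.4% ± 3.40. PHYA (AT1G09570) retained intron 1 at 11.8% ± 2.97 and SPA1 (AT2G46340) at 4.54% ± 1.07.

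None of the 5 stress-response genes listed had a shifted site, a skip or a CRIN event (Fisher's exact p = 0.0166, adjusted 0.0538). HSP101 (AT1G74310), a heat shock protein, retained intron 5 at 47.4% ± 19.1 (80 retained reads in all), and DREB2A (AT5G05410) retained intron 1 at 15.8% ± 8.05 (21 retained reads), BZIP60 (AT1G42990) at 9.63% ± 2.11 and COR15A (AT2G42540) at 4.12% ± 2.79. HSFA2 (AT2G26150) had a CREX event at 32% ± 11.1, resting on 9 reads, and no listed retained intron. Among immune genes 2 of 6 had such an event (Fisher's exact adjusted p = 0.716). SNC1 (AT4G16890) retained intron 5 at 99.8% ± 0.154, PAD4 (AT3G52430) intron 1 at 84.5% ± 2.15, RPP4 (AT4G16860) intron 1 at 68.5% ± 4.99, RRS1 (AT5G45260) intron 5 at 47.4% ± 6.85, RPS4 (AT5G45250) intron 3 at 27.5% ± 11.4 (39 retained reads) and EDS1 (AT3G48090) intron 2 at 2.83% ± 0.477. Of 4 small RNA genes, 2 had such an event (Fisher's exact adjusted p = 1): an acceptor of AGO1 (AT1G48410) removed 6 nt at 45.8% ± 4.28, and a donor of DCL1 (AT1G01040) removed 3 nt at 80.2% ± 2.41. DCL1 retained intron 14 at 56.7% ± 8.47, SE (AT2G27100, SERRATE) intron 3 at 19.8% ± 3.61, HYL1 (AT1G09700) intron 1 at 7.21% ± 1.29 and AGO1 intron 10 at 1.70% ± 0.537.

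Among cell type markers, a shifted site, a skip or a CRIN event was found in 1 of 3 guard cell genes (MYB60; adjusted 0.762), 1 of 1 trichome gene (GL2; adjusted 1), 1 of 3 vascular genes (XCP1; adjusted 0.762), 1 of 2 epidermal genes (ATML1; adjusted 1) and 0 of 1 floral gene (AG; adjusted 0.716), all by Fisher's exact test. Intron 1 of GL2 (AT1G79840) was retained in all 44 reads and that of ATML1 (AT4G21750) at 73.9% ± 11.3, while CER6 (AT1G68530) retained intron 1 at 11.5% ± 4.52. In guard cell genes, MYB60 (AT1G08810) retained intron 2 at 31.9% ± 1.28, FAMA (AT3G24140) intron 5 at 23.9% ± 7.23 and KAT1 (AT5G46240) intron 7 at 6.93% ± 2.05. In vascular genes, ATHB8 (AT4G32880) retained intron 4 at 16.3% ± 7.62 and SUC2 (AT1G22710) intron 2 at 8.98% ± 2.77, and XCP1 (AT4G35350) had no listed retained intron and a donor shift at 0.798% ± 0.311. AG (AT4G18960), a floral organ gene, retained intron 2 at 27.6% ± 5.80 on 12 reads. None of the 4 shoot meristem and 3 seed storage markers was listed.

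Duplicated genes less often had a listed event than single-copy genes, and shifted acceptors showed the largest gap. Any event was listed for 63.5% of duplicated genes and 67.1% of single-copy genes matched on intron number (permutation p = 1e-04, the smallest possible; adjusted over 7 comparisons 0.000233). Expression was not matched here, since unlisted genes have no depth. In this comparison, a difference in leaf expression or in the placing of reads cannot be told apart from one in splicing. Among genes with a junction-level event, a shifted site, a skip or a CRIN event was present in 53.7% of 10,298 duplicated genes and 60.5% of single-copy genes matched on depth and intron number, and a shifted acceptor in 35% and 42.9% (permutation p = 1e-04 for both, the smallest possible; adjusted 0.000233). Shifted donors were present in 24.5% and 27.1% (permutation p = 0.0079, adjusted 0.0138) and shifts of both sites in 7.32% and 8.26% (permutation p = 0.0234, adjusted 0.0328). Skipped exons (5.97% and 6.67%, permutation p = 0.152, adjusted 0.177) and CRIN (9.36% and 9.56%, permutation p = 0.666, adjusted 0.666) did not differ by this test. Without matching, 5531 of 10,301 duplicated and 2280 of 3658 single-copy genes had such an event (Fisher's exact p = 1.27e-19). With at least 10 reads per library, the donor gap (-1.48 points, permutation p = 0.136) and the ALTP gap (0.112 points, permutation p = 1) were not called.

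Where an event class was listed in a duplicate pair, it was mostly listed in 1 member only, but less often so than in random matched pairs. Among the 2927 pairs, 1256 had a shifted acceptor in neither member, 1651 no shifted donor, 2523 no ALTP, 2566 no SKIP and 2422 no CRIN event. Of 1671 pairs with a shifted acceptor in at least 1 member, 1100 (65.8%) had it in 1 member only, against 72.4% of random pairs (95% range 70.6 to 74.0%; permutation p = 1e-04, the smallest possible; adjusted over 8 comparisons 0.00016). For shifted donors the shares were 77.6% of 1276 pairs and 82.3% (permutation p = 1e-04, the smallest possible; adjusted 0.00016), for ALTP 90.1% and 94.4% (permutation p = 0.0002, adjusted 0.000267), for SKIP 92.0% and 95.6% (permutation p = 0.0004, adjusted 0.000457) and for CRIN 93.1% and 95.3% (permutation p = 0.0132, adjusted 0.0132). Of 15,396 homologous introns, 5274 had no listed retention, 13,591 no shifted acceptor and 14,382 no shifted donor in either member. At these introns, 5907 of 10,122 retained introns (58.4%) were listed in 1 member only, against 67.7% of random introns, and the shares were 87.7% and 96.2% for shifted acceptors and 91.3% and 98.0% for shifted donors (permutation p = 1e-04 for each, the smallest possible; adjusted 0.00016). Under 2 settings a call ended: SKIP with at least 10 reads per library (-1.56 points, permutation p = 0.480) and CRIN in pairs under 90% identity (-0.664 points, permutation p = 0.538). Near-identical copies may share reads, and a class missing from a member is not detected at this depth rather than absent.

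**Figure D4:**
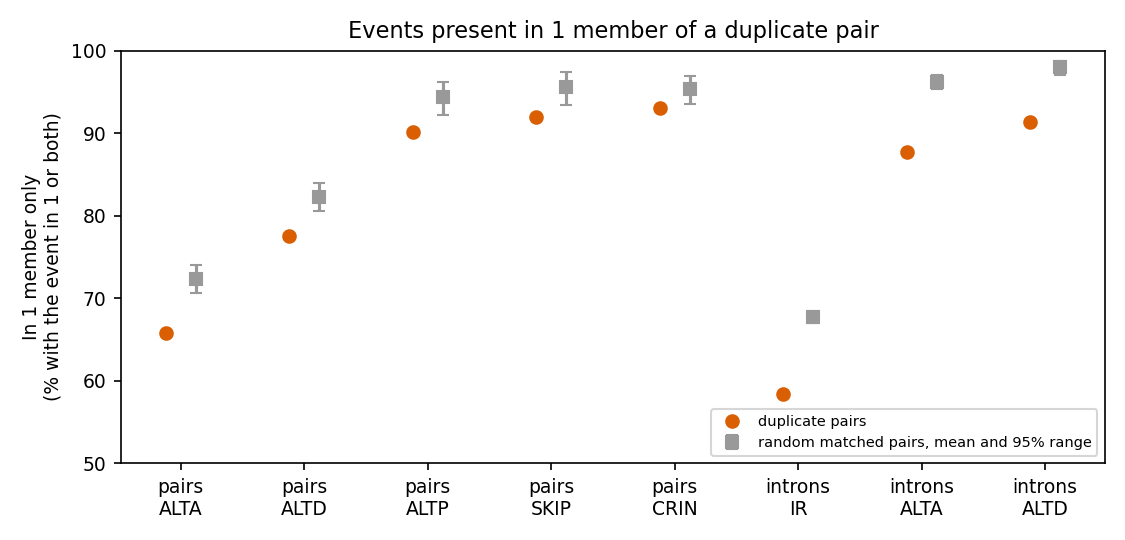
Percent of duplicate pairs (first 5 columns) or homologous introns (last 3) with an event in 1 member only, among those with it in 1 or both. Orange points are duplicates, and grey squares are random matched pairs with the 95% range of 10000 draws. Introns were matched on depth alone. Duplicates lie below random pairs in all 8 comparisons, from 58.4% against 67.7% for retained introns to 93.1% against 95.3% for CRIN.

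Where both members had the same class at a homologous intron, the level differed in many pairs, including splicing-factor and clock genes. Intron 4 of U2AF65b (chromosome 1, 22425297 to 22425926) was retained at 68.5% ± 9.36 and that of U2AF65a (chromosome 4, 17296227 to 17296659) at 6.49% ± 2.84, a log2 odds difference of 5.08 ± 0.31 (SE, limma adjusted p = 0.00215). Intron 4 of CCA1 was retained at 50.8% ± 15.7 and the homologous intron 5 of LHY (AT1G01060, chromosome 1, 35964 to 36623) at 2.28% ± 1.12 (log2 odds of LHY over CCA1 -5.37 ± 0.61, limma adjusted p = 0.00474). MAF3 (AT5G65060) used a shifted acceptor at intron 3 (chromosome 5, 25990004 to 25990083) at 41.7% ± 3.39 and MAF2 (AT5G65050) at 3.77% ± 0.767 (limma adjusted p = 0.00274), while MAF2 retained that intron more, at 71.8% ± 2.06 against 43.4% ± 3.02 (limma adjusted p = 0.0164). MYB59 (AT5G59780) shifted the donor of intron 1 at 21% ± 1.09 and MYB48 (AT3G46130) at 1.52% ± 0.415 (limma adjusted p = 0.00278). MYB48 retained intron 1 at 96.1% ± 1.77 against 76.9% ± 1.92 in MYB59, and intron 2 at 34.8% ± 7.58 against 12.7% ± 2.17 (limma adjusted p = 0.00654 and 0.0249). Classes at 1 intron share 1 total, so a higher level of 1 class lowers the others. The 2 calls at intron 3 of MAF2 and MAF3, and those at intron 1 of MYB48 and MYB59, are therefore not independent. The shifted sites of these 2 pairs were not matched by position, and their levels are relative to the site annotated in each gene. RS2Z32 retained intron 2 more than RS2Z33 (52.7% and 16.9%, limma adjusted p = 0.00675), RS31a (AT2G46610) more than RS31 (AT3G61860; 72.6% ± 3.70 and 43.1% ± 6.45, limma adjusted p = 0.0232), GRP7 intron 1 more than GRP8 (44.1% and 23.6%, limma adjusted p = 0.032), PTB2 (AT5G53180) intron 3 more than intron 2 of PTB1 (AT3G01150; 25.8% ± 11.6 and 9.68% ± 3.76, limma adjusted p = 0.0239) and CAT1 (AT1G20630) intron 2 more than CAT3 (AT1G20620; 8.42% ± 0.898 and 0.237% ± 0.0435, limma adjusted p = 0.0022). Each of these differences had the same direction in 3 of 3 libraries. RS40 and RS41 did not differ at intron 2 by this test (33.8% and 30.0%, log2 odds 0.26 ± 0.31, limma adjusted p = 0.528).

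**Figure D5:**
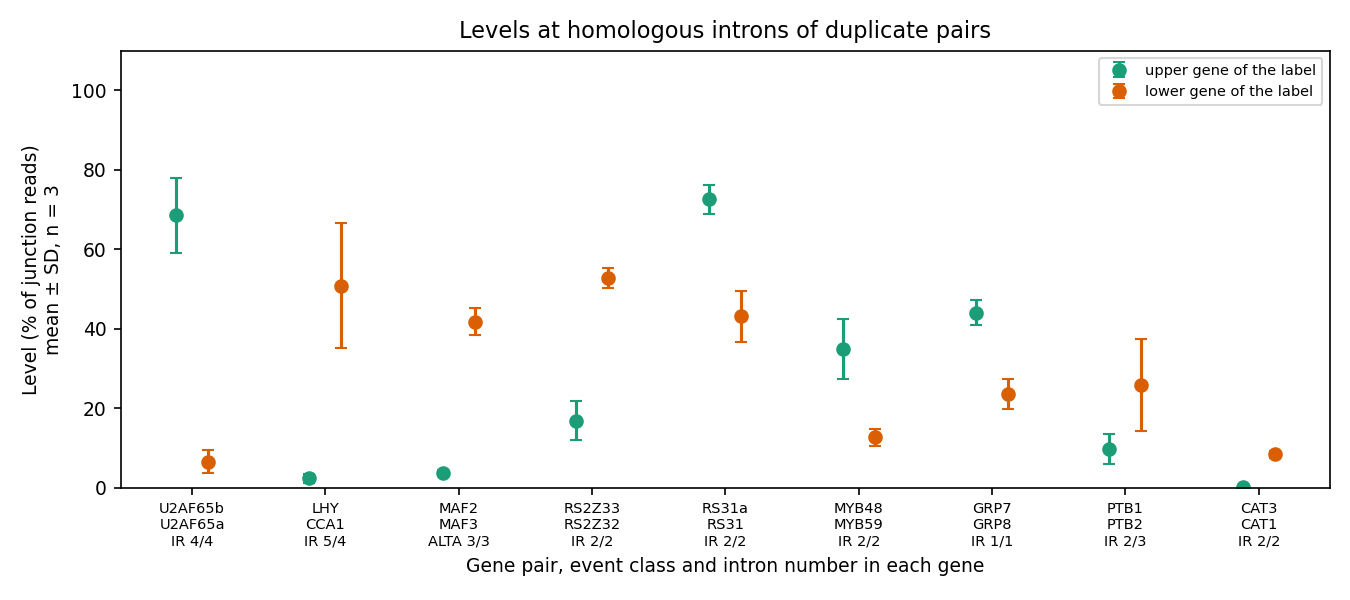
Levels in percent of junction reads (mean ± SD, n = 3) at the homologous intron with the largest called difference, for the 9 preset pairs with a difference of at least 5 points; green is the upper and orange the lower gene of each label, followed by the class and the intron number in each gene. The widest gaps are those of U2AF65b over U2AF65a (68.5% and 6.49%) and CCA1 over LHY (50.8% and 2.28%).

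Of the 28 preset pairs, 27 had both members in the table and 20 had introns that could be compared, with 40 of 70 comparisons called in 17 pairs and 12 of them by 10 points or more. Calls in the abundant photosynthesis pairs were small in points, but not all were small in log2 odds. At intron 2 of CA1 and intron 3 of CA2 (0.0556% and 1.75%) the log2 odds of CA1 over CA2 were -5.25 ± 0.49 (SE). At intron 4 of GAPA2 over GAPA1 they were 1.44 ± 0.33. All called retained introns of CA1 were at most at 0.688% ± 0.343 against up to 5.14% ± 1.46 at their counterparts in CA2, PSBO1 (AT5G66570) and PSBO2 (AT3G50820) intron 1 at 1.84% ± 0.404 and 0.671% ± 0.155, and GAPA1 (AT3G26650) and GAPA2 (AT1G12900) intron 4 at 0.459% ± 0.194 and 1.19% ± 0.285 (limma adjusted p = 0.0265). NIA2 (AT1G37130) retained intron 2 at 3.58% ± 2.57 and NIA1 (AT1G77760) at 0.302% ± 0.266 (limma adjusted p = 0.00773). LHCB4.1 (AT5G01530) and LHCB4.2 (AT3G08940) retained intron 1 at 3.79% ± 0.515 and 1.32% ± 0.649 (limma adjusted p = 0.0234), and RBCS2B (AT5G38420) and RBCS3B intron 2 at 0.646% ± 0.0738 and 0.236% ± 0.102 (limma adjusted p = 0.0401). AFB1 (AT4G03190) retained intron 2 at 4.11% ± 1.19 and TIR1 (AT3G62980), both auxin receptors, at 1.12% ± 0.860 (limma adjusted p = 0.0341). RS40 and RS41 differed at intron 4, at 1.55% ± 1.46 and 0.193% ± 0.0781 (limma adjusted p = 0.0475). No intron of LHCB2.1 and LHCB2.2, of ACT2 and ACT8 or of RSZ22 and RSZ22a was called. The near-identical copies among these pairs, such as LHCB2.1 and LHCB2.2 or RBCS2B and RBCS3B, may share reads. No intron could be compared in PSAD1 and PSAD2, LHCB1.1 and LHCB1.2, U2AF35a and U2AF35b, SCL30a and SCL33, SR34 and SR34b, EIN3 and EIL1, HY5 and HYH or PHYB and PHYD. With 1 library left out, several of the calls named above were lost. The limma adjusted p rose to 0.0922 without replicate 2 and 0.102 without replicate 3 for RS31a and RS31, to 0.0730 without replicate 2 and 0.0921 without replicate 3 for the retained intron 3 of MAF2 and MAF3, to 0.0855 without replicate 1 and 0.113 without replicate 3 for intron 2 of MYB48 and MYB59, and to 0.0809 without replicate 1 and 0.116 without replicate 3 for PTB1 and PTB2. It rose to 0.113 without replicate 2 and 0.135 without replicate 3 for TIR1 and AFB1, to 0.0974 and 0.112 for LHCB4.1 and LHCB4.2 without the same libraries, and to 0.115 without replicate 1 and 0.140 without replicate 3 for intron 4 of RS40 and RS41. For GRP7 and GRP8, intron 2 of RBCS2B and RBCS3B, intron 1 of PSBO1 and PSBO2 and intron 4 of GAPA1 and GAPA2 it exceeded 0.05 whichever library was left out (for GRP7 and GRP8 0.0555, 0.131 and 0.142).

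Over all pairs, limma called 2131 of 4525 comparisons (47.1%) in 1353 gene pairs, 2130 of them with the same direction in all 3 libraries. They comprised 1999 of 4215 retained introns, 103 of 222 shifted acceptors and 29 of 88 shifted donors. The median difference among calls was 8.66 points, and 981 reached 10 points. An intron enters this test only with at least 1 read of the class in every library in both members. A member with few junction reads therefore enters only at a high level. The count of calls and their median difference include this selection. The count was 1227 without replicate 3 and 391 of the comparisons with at least 10 reads in each library. Outside the preset pairs, the 10 largest differences included 3 with many reads in both members: an acceptor at intron 16 of AT1G01320 (chromosome 1, 125047 to 125133) at 99.4% ± 0.141 against 0.120% ± 0.115 in AT4G28080, a donor at intron 1 of AT3G17800 (chromosome 3, 6092565 to 6092711) at 99.4% ± 0.558 against 0.561% ± 0.129 in AT1G48450, and an acceptor at intron 5 of AT4G26860 (chromosome 4, 13503630 to 13503700) at 99.0% ± 0.711 against 0.541% ± 0.655 in AT1G11930 (limma adjusted p = 0.00141, 0.00227 and 0.00141). These shifted-site levels count all reads away from the site annotated in each gene. Such a difference can arise from which site is annotated, and no common site was compared between the members. In 3 others the retained member had few junction reads and many reads of a skip that spans the intron. With the skip reads added, the level fell from 99.6% to 2.39% in AT2G27720 (161 junction and 6548 skip reads; AT2G27710 0.347%), from 100% to 0.542% in DSS1(I) (24 and 4405; DSS1(V) 1.02%) and from 100% to 0.632% in AT5G02610 (38 and 5970; AT2G39390 1.17%). A further 3, AT5G20940 over AT5G20950, TMT3 over TMT2 and CRK8 over CRK6, rested on 12, 6 and 4 reads in the member at 100%.

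Tandem pairs were not separated from other pairs by either test. A shifted acceptor or a shifted donor was listed in 1 member only in 144 of 192 tandem pairs (75.0%) and 1519 of 1858 other pairs (81.8%; Fisher's exact p = 0.0259, adjusted over 2 tests 0.0518). The mean absolute log2 odds difference of retained introns was 1.89 in 206 tandem and 1.93 in 1859 other pairs (permutation p = 0.707, adjusted 0.707).

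Most duplicate pairs also differed in the reads of their median junction, taken over junctions with a listed event. Skip reads are not part of these totals, so genes with much skipping can be understated. An example is AT2G27720, with 161 junction and 6548 skip reads at intron 2. Limma called 2392 of 2927 pairs (81.7%), and 1355 of these differed at least 2-fold. The median absolute log2 difference was 1.15 among called pairs and 0.92 among all. Only pairs with a listed event in both members enter this count, which leaves out the 1490 pairs with 1 member in the table.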

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

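Of the tests in this part, those of depth, genomic DNA and unspliced RNA in replicates 1 and 2 and that of counting noise at high retention, as well as the counts with organellar copies taken once, were chosen only after the result was seen.

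Signals outside the comparisons came from the organellar genomes, which are in the table but in none of the tests. Retained introns of the chloroplast had a median level of 99.5% (24 IR events among 38 events in 27 genes) and those of the mitochondrion of 98.3% (18 IR events among 22 events in 12 genes). Copies in the chloroplast's inverted repeat share reads, so their events are not independent.

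Nuclear retained introns that differed between libraries were lowest in replicate 2 in 2791 of 5241 cases. A highest level in replicate 1 was not particular to them. It was found in 3075 of 5241 called IR, 263 of 446 ALTA, 155 of 272 ALTD and 115 of 179 CRIN events, but in 31 of 108 SKIP events. Of the called ALTA, ALTD and CRIN events, 126, 88 and 89 were lowest in replicate 2. Depth and the listing of events with at least 1 read in each library would leave no shift among well-covered introns, but with at least 10 retained reads the median log2 ratio of replicate 1 to replicate 2 was 0.138 (0.125 to 0.147, 13,142 introns), which argues against depth as the whole cause. Genomic DNA would weigh least at the most expressed junctions, but the ratio there was the highest of the 10 depth bins, 0.431 (0.391 to 0.474). More unspliced RNA in replicate 1 stays open. Organellar retained reads were higher in CPM in replicate 1 than in 2 at 37 of 42 introns (1882 against 658 CPM summed). With copies whose reads differ by at most 1% counted once, this held at 32 of 37 (1187 against 466 CPM). Without the 2 of these with the most reads in replicate 1, it held at 30 of 35 (578 against 332 CPM), and in the mitochondrion at 13 of 18 (151 against 133 CPM). As nearly all reads at these introns are retained ones, the counts follow the organellar share of the library and decide nothing. No biological explanation was tested, since the labels give 1 group, and a difference in harvest or RNA extraction stays open.

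Retention of 90% or more was found at 1682 nuclear introns. Counting noise would spare introns with at least 10 retained reads in each library, of which 7.41% reached 90% (6.97 to 7.87%), so it does not account for these. An exon of another annotated transcript covers 29.9% of the 1472 introns at 90% or more with assigned coordinates (27.6 to 32.3%), against 4057 of 40,541 introns at lower levels, which may account for a part but not for most, and 252 of the 1682 (15.0%) fall under 50% once reads of listed skips are added to the total. Whether leaf transcripts hardly use these annotated junctions stays open: their reads were 96.1% of the median junction of the gene (median, 88.9 to 100%, 1059 introns), but this total is mostly the retained reads themselves and decides nothing. No biological explanation was tested, and the unknown counting of intron reads stays open.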

How the results depend on the processing

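Chosen only after the result was seen were the settings with at least 5 expected reads, skip reads added, pairs under 90% identity, stricter pairs for expression and gene lists with a shifted site at 10% or more; the others were fixed in advance. Of the alternative values of the main results, 163 kept their direction and side of the threshold or moved by less than their spread, 20 moved, 4 lost their call and 6 turned. Because every event has reads in each library, leaving out a library cannot change which events are listed. Class shares, the 1-member share of tandem pairs and Fisher's exact tests of gene lists are therefore fixed there by construction. For duplicated against single-copy genes and for events in 1 member of a pair, at most the depth strata used for matching can move. The 163 include such fixed values. The cause of the changes given here was not tested except where the smaller number of libraries or tests is the setting itself.

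With at least 10 reads in each library the class shares moved to 72.0% IR, 12.8% ALTA, 7.33% ALTD, 2.09% SKIP and 3.4% CRIN, and with each gene counted once per class to 51.6%, 19.7%, 13.3%, 3.31% and 6.22%. The same minimum raised the median levels to 11.3% (IR), 18.3% (ALTA) and 17.2% (ALTD) and turned the differences to -6.91 (IR minus ALTA), -5.83 (IR minus ALTD) and -1.08 points (ALTD minus ALTA). This minimum on alternative reads selects on the level itself. It also ended the duplicated against single-copy gap for ALTD (-1.48 points), turned that for ALTP (0.112 points), ended the SKIP call of duplicate pairs (-1.56 points) and left 391 of 695 intron pairs called. Without 1 library, ALTD minus ALTA ranged from 0.200 (replicate 1 left out, permutation p = 0.0663) to 0.247 points, intron pairs called from 1227 to 1588 and homogeneity calls from 2042 to 3755; the tandem difference in absolute log2 odds ranged from -0.0677 to 0.00163, and was 0.11 with adjacent genes only. CRIN in duplicate pairs under 90% identity lost its call (-0.664 points). Of the 3 gene lists called, 1 passed with a depth-matched background and 0 with a shifted site at 10% or more, where 2 lists had an unadjusted Fisher's exact p under 0.05: circadian clock genes (28.9 points, p = 0.00977, adjusted 0.127) and SR proteins (21 points, p = 0.0425, adjusted 0.276).

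Of the 2131 intron calls, 2083 kept their direction and call with the larger pseudocount and 2083 with skip reads added, where 27 turned; 304 of 305 that could be tested with at least 10 reads kept theirs, as did 1483, 1430 and 1200 without replicate 1, 2 and 3. Among named intron pairs, uncalled differences in log2 odds turned for RSZ22a and RSZ22 intron 3 (-0.0871) and CAT3 and CAT1 intron 1 (-0.216) with the larger pseudocount and for 10 comparisons when 1 library was left out. With 1 library left out the values ran from -0.0688 to 0.366 for intron 3 of RSZ22a and RSZ22, from -1.19 to 0.76 for IR and -0.59 to 0.50 for ALTA at intron 4 of MAF2 and MAF3, from -0.12 to 0.75 for ALTA at intron 4 of GAPA2 and GAPA1, from -0.18 to 0.65 for intron 1 of NIA2 and NIA1, from -1.07 to 0.28 for intron 5 of PTB1 and PTB2, from -0.17 to 0.46 for intron 1 of RBCS3B and RBCS2B, from -0.0552 to 0.607 for intron 3 of ACT8 and ACT2, and from -0.0233 to 0.567 (intron 1) and -0.76 to 0.14 (intron 4) for CAT3 and CAT1. With skip reads added, DSS1(I) and DSS1(V) turned to -0.83, AT2G39390 and AT5G02610 to 0.75 and MAF2 and MAF3 intron 1 to 0.31, as the totals of the spanned junctions grew. The small RNA list turned to 26.9 points (at least 10 reads) and 28.9 points (site at 10% or more), and the photosynthesis list to -12.4 points (site at 10% or more). Leaving out replicate 1, 2 or 3 ended 17, 16 and 23 calls of named intron pairs, with 2 libraries left in the test. An event needs 1 read in each library to be listed, and at a median junction a count of 0 allows a level of up to 1.66%, 1.70% and 0.990% in replicates 1, 2 and 3.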

Other observations

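Of the tests in this part, that of the member with more reads was chosen only after the result was seen.

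Shifted acceptors that reached a high level in coding regions kept the reading frame more often. Among 1757 ALTA events in coding regions with a level of 10% or more, 52.3% had a length divisible by 3, against 31.2% of 5556 events at lower levels, an odds ratio of 2.42 (2.16 to 2.69, Fisher's exact p = 2.39e-56, one-sided). Outside coding regions the shares were 42.8% and 36.8% (odds ratio 1.28, 1.01 to 1.63), and the ratio of the odds ratios was 1.88 (1.44 to 2.46). Without 3-nt shifts the coding shares were 37.7% and 25.9%. A candidate explanation is that the reading frame limits which shifts reach a high level, for example through decay of out-of-frame transcripts, which was not measured.

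Of 1499 events with both sites shifted, 402 (26.8%) moved donor and acceptor by the same length. The introns they imply began with GT or GC and ended with AG in only 10.2% of cases (7.42 to 13.6%), against 56.8% of the other ALTP events, which is consistent with reads placed a few bases off by the aligner. The 361 without these ends had a median level of 0.0899% at junctions with a median of 2577 reads per library, and the 41 with them a median level of 43.6%.

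The prediction that the member of a duplicate pair with more junction reads is the less retained one was not met, but the test cannot decide it. With a floor set at the shallower member's depth, the member with more reads had the lower level in 270 of 525 gene pairs (51.4%, 47.1 to 55.8%, exact binomial p = 0.541). Junction reads hold the retained reads themselves, so higher retention adds to a member's depth and works against the prediction. An earlier form of the test, with at least 10 retained reads required of both members, gave 293 of 451 (65%), but that requirement itself selects higher levels in the shallower member, and it was replaced after its result was seen.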
